A study of Rattus norvegicus with 12 samples.

How the data were processed

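Total RNA came from cardiomyocyte-enriched cultures of newborn Sprague-Dawley rat ventricles, collected 48 h after transfection. Per the labels' protocols, RNA was amplified with the Ovation RNA-Seq v2 system, made into libraries with Nextera XT, and read in pairs on an Illumina HiSeq instrument. The submitters' processing notes name FastQC, Trim Galore, cutadapt, STAR and featureCounts and the rat build rn5, with no versions. Strand setting, gene annotation and counting options are not given in the sources used here.

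The authors deposited raw counts per gene, whole numbers for 17419 gene symbols in 12 libraries, and a table of TPM values. In the deposited TPM table each gene's values were proportional to its counts over a fixed length, to within 1.11% in 7126 well-counted genes, with values rounded to 0.1. Among counts of 1 to 10, 13201 were even and 10440 odd, a pattern that counting both mates of a read pair would leave, so counts can exceed the number of fragments. Amplified RNA without molecular identifiers gives reads that are not independent molecules. Gene names are those in the deposited table: 17074 matched the symbols or synonyms of the RefSeq table of the rat assembly GRCr8 and 345 did not. That assembly differs from rn5, so no coordinates are printed.

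Groups came from the sample titles and treatment labels, 3 libraries in each of 4 groups. No group held identical libraries: chi-square per degree of freedom between replicates, over genes with at least 100 counts, ran from 4.07 to 25.7, the highest between replicates 1 and 3 of the double knockdown. Pearson correlations of log2 CPM between replicates were 0.997 to 0.998. The ribosomal RNA gene Rn45s took 0.876 to 1.49% of the counts in the libraries where it was the top gene, and the top 10 genes took 5.35 to 6.55%.

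The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts with robust dispersions, TMM scaling and 1 mean per group, all 12 libraries in one fit with 8 residual degrees of freedom. The filter filterByExpr kept 12535 genes and removed 4884. TMM factors ran from 0.971 to 1.02, and the common biological coefficient of variation was 4.97%. P-values were adjusted by Benjamini-Hochberg within each of 7 comparisons and called at 0.05. Standard errors are the log2 change over the square root of F. CPM are TMM-scaled, and 1 count was worth 0.0216 to 0.0409 CPM. TMM scaling assumes that most genes do not change, and up to 40.8% of genes were called in a comparison, mostly with small changes.

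Genes were named by a rule set before the data were examined: Btg1 and Btg2 always, and the 10 largest rises and 10 largest falls in the double knockdown against scramble (5 and 5 elsewhere). These had to pass the test, average at least 5 CPM in the groups compared, show no overlap between groups (not asked of the interaction) and have an established symbol. From each of 26 lists (19 pathways, 7 sets of cell type markers), also fixed before, up to 4 members with the smallest p were eligible. Some genes that this rule names are not reported here. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. List counts use the adjustment over all tested genes, and those adjusted over the list alone are given where they differ. A list's median, mean and camera direction differed in sign only where the list did not pass camera. Myl4 and Myl7 belong both to the sarcomere list and to the atrial genes added later. Nppa, Sln and Kcnj3 (atrial) and Cdkn1c (imprinted) also belong both to planned and to added lists. Planned lists overlap too, so they are not independent. Myh7 is in the sarcomere and hypertrophic lists, Ankrd1 in the hypertrophic and YAP lists, and Cdkn1a in the inhibitor and p53 lists.

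Alternatives set before the data were examined were DESeq2 1.42.0, RLE scaling, library size alone, no filter, a filter of 1 CPM in 6 libraries, only the groups compared, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library. On counts simulated from the libraries' means and sizes, with 217 genes changed between the scramble and double knockdown groups among 12535, the edgeR step recovered 59 of 66 genes changed 2-fold, 52 of 67 changed 1.5-fold and 34 of 67 changed 1.2-fold. A limit of 90% recovery at 2-fold had been set and was missed at 89.4%. The check was then restated to apply from 1 CPM, where 59 of 59 were recovered; the 7 missed genes all lay below 1 CPM. Departure from additive effects was also tested by permuting the residuals of an additive limma fit on log2 CPM, a test added after the results were seen. In the simulation 12 of 173 calls (6.94%) were false.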

Results

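RNA was measured in primary cultures of neonatal rat ventricular cardiomyocytes, the contractile cells of the heart, 48 h after transfection with small interfering RNA (siRNA). The siRNA targeted Btg1, Btg2 or both, a pair of related genes of the BTG/TOB family whose proteins restrain proliferation and bind the CCR4-NOT deadenylase complex. Control cultures received 20 nM of a scrambled siRNA. Single knockdowns received 10 nM of the Btg1 or the Btg2 siRNA with 10 nM of scramble. Double knockdowns received 10 nM of each targeting siRNA and no scramble. Each of the 4 groups had 3 libraries. Total counts were 33248851, 39128757 and 35782768 in scramble replicates 1 to 3 and 46206581, 37574625 and 34823651 in the Btg1 knockdown. They were 39286008, 24434925 and 41706601 in the Btg2 knockdown and 36727943, 38039774 and 40205757 in the double knockdown. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

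The targeted transcripts were lower in the groups that received their siRNA. Btg1 stood at 283 ± 2.19 CPM in scramble cultures (SD, n = 3), 66.2 ± 4.07 in the Btg1 knockdown, 299 ± 4.70 in the Btg2 knockdown and 51.7 ± 2.41 in the double knockdown (SD, n = 3 each). This left 23.4% of the scramble level in the Btg1 knockdown and 18.3% in the double knockdown. Btg2 stood at 139 ± 6.41 CPM in scramble cultures, 175 ± 5.0 in the Btg1 knockdown, 85.2 ± 2.31 in the Btg2 knockdown and 68.7 ± 0.983 in the double knockdown (SD, n = 3 each). The Btg2 siRNA thus left 61.5% of the Btg2 transcript alone and 49.6% in the double knockdown, while Btg2 in the Btg1 knockdown was at 127% of scramble.

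Library by library, Btg1 was at 285, 281 and 284 CPM in scramble replicates 1 to 3, at 69.9, 61.8 and 66.8 with the Btg1 siRNA, at 296, 305 and 297 with the Btg2 siRNA, and at 50.9, 54.4 and 49.8 with both. Btg2 was at 140, 132 and 144 CPM in scramble, 170, 179 and 177 with the Btg1 siRNA, 82.8, 85.3 and 87.4 with the Btg2 siRNA, and 69.6, 67.6 and 68.8 with both. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Btg1 changed by -2.10 ± 0.04 on the log2 scale in the Btg1 knockdown (SE, adjusted p = 6.4e-20) and by -2.45 ± 0.05 in the double knockdown (adjusted p = 3.0e-21). In the Btg2 knockdown its change of 0.08 ± 0.04 did not pass (edgeR adjusted p = 0.16). Btg2 changed by -0.70 ± 0.04 in the Btg2 knockdown (edgeR adjusted p = 6.8e-11), by -1.01 ± 0.04 in the double knockdown (adjusted p = 3.5e-14) and by 0.34 ± 0.04 in the Btg1 knockdown (adjusted p = 7.5e-07).

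**Figure D1:**
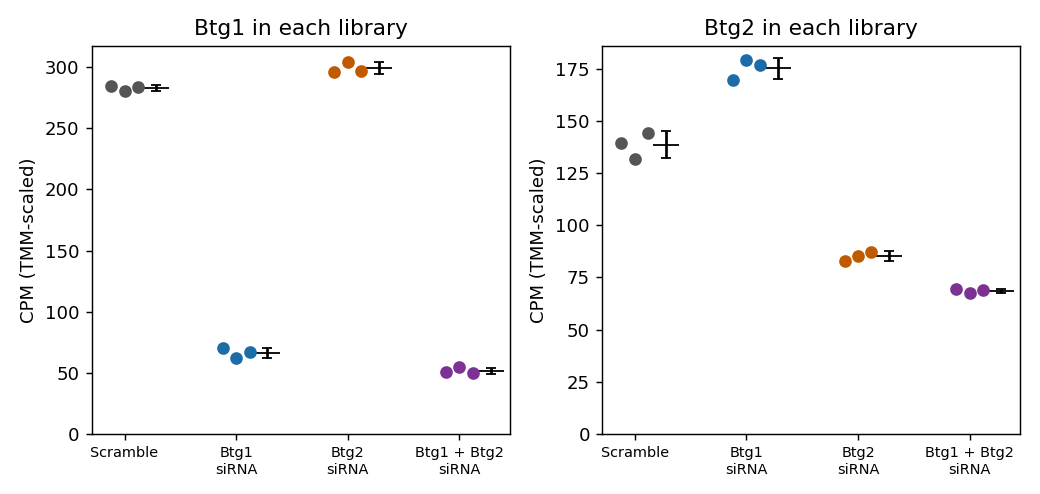
CPM of Btg1 (left) and Btg2 (right) in each of the 12 libraries by group, points for libraries and bars for the mean with its SD (n = 3). Btg1 lies between 49.8 and 69.9 CPM in the libraries that received its siRNA and between 281 and 305 in the others, and Btg2 lies between 67.6 and 87.4 in those that received its siRNA and between 132 and 179 in the others.

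The 12 libraries grouped by siRNA. On a principal component analysis of log2 CPM, the first component held 30.1% of the variance and placed the 6 libraries with the Btg1 siRNA at 11.6 to 20.4 and the 6 without it at -17.8 to -13.8. The next component held 17.5% and placed the 6 libraries with the Btg2 siRNA at -13.3 to -7.77 and the others at 7.12 to 17.2. Of 12535 genes tested by edgeR's quasi-likelihood method with all 12 libraries in one fit, between 1890 and 5120 passed an adjusted p of 0.05 in each of 7 comparisons. Most changes were small: the median absolute log2 change of the genes that passed was 0.29 in the double knockdown against scramble.

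**Figure D2:**
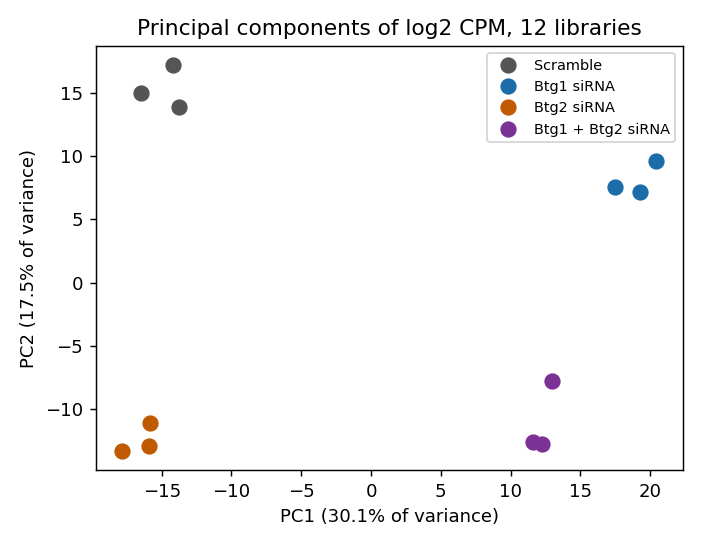
First and second principal components of log2 CPM over the 12535 tested genes, 1 point per library, coloured by group. The libraries with the Btg1 siRNA lie to the right (11.6 to 20.4 on the first component) and those with the Btg2 siRNA lie below 0 on the second (-13.3 to -7.77).

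**Figure D3:**
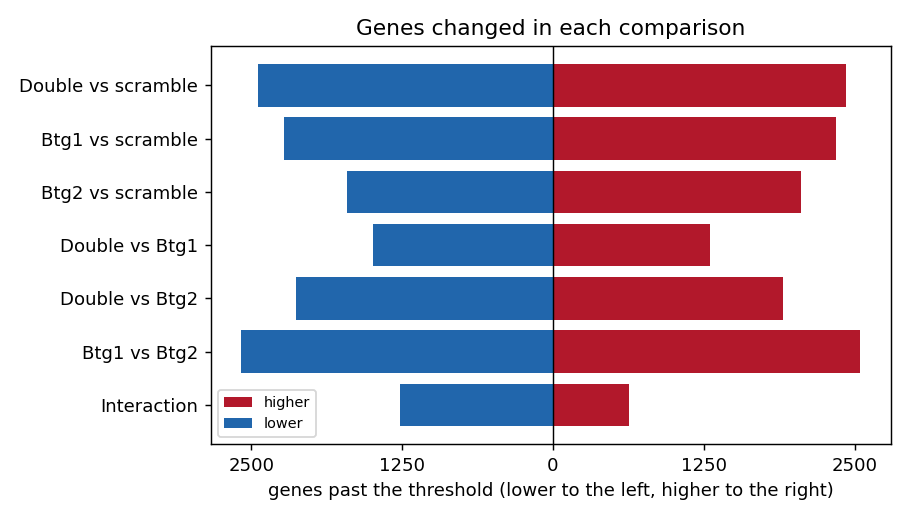
Number of genes past an adjusted p of 0.05 by edgeR in each comparison, with higher genes to the right and lower genes to the left. The Btg1 against Btg2 comparison had the most (2540 higher, 2580 lower), and the interaction had the fewest (626 higher, 1264 lower).

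Double knockdown against scramble asked what changed when both transcripts were reduced. The light chain gene Myl4, the atrial and fetal essential myosin light chain, rose from 58.5 ± 0.630 to 176 ± 16.9 CPM (SD, n = 3 each). Inha, the inhibin alpha subunit, rose from 48.9 ± 1.89 to 139 ± 3.39 CPM, and the smooth muscle actin-binding protein gene Cnn1 rose from 63.6 ± 5.29 to 145 ± 8.10 CPM (SD, n = 3 each). Sgcb, the beta-sarcoglycan of the dystrophin complex, fell from 317 ± 7.40 to 115 ± 5.95 CPM, and Atp1b2, a sodium pump beta subunit, fell from 184 ± 8.66 to 73.0 ± 0.523 CPM (SD, n = 3 each). Genes of DNA replication and mitosis, fibroblast and endothelial markers and unfolded protein response genes mostly fell, while interferon response and sarcomere genes mostly rose.

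Of the genes with the largest changes and no overlap between the 3 libraries of each group, which chance alone gives 10% of genes, the other rises were Reep6 (log2 change 1.83 ± 0.16, SE), the keratin gene Krt80 (1.60 ± 0.14), the imprinted noncoding RNA H19 (1.36 ± 0.12), Lmcd1 (1.32 ± 0.13), the clathrin assembly gene Snap91 (1.24 ± 0.16) and the small GTPase gene Rac2 (1.19 ± 0.08). Mir675 (1.38 ± 0.14) lies within H19, so reads of the one cannot be told from reads of the other and its value is uncertain. The largest falls beside Btg1 and the genes above were the scavenger receptor gene Colec12 (-1.92 ± 0.09), Capn6 (-1.82 ± 0.16), Emc4 of the endoplasmic reticulum membrane complex (-1.75 ± 0.06), the neurotrophin gene Bdnf (-1.43 ± 0.12), Tceal1 (-1.37 ± 0.09), the mitochondrial carrier gene Slc25a34 (-1.29 ± 0.09) and Leprotl1 (-1.25 ± 0.08). Their edgeR adjusted p-values ran from 1.6e-17 for Sgcb to 2.3e-04 for Snap91.

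Among 33 tested genes of G2/M and mitosis, 19 fell and 2 rose (21 and 2 adjusted over the list alone), with a median log2 change of -0.33. Kif23 (-0.88 ± 0.11), Cdc20 (-0.54 ± 0.07) and Aurkb (-0.70 ± 0.11) fell, and Cenpf, a kinetochore gene, rose by 0.46 ± 0.07. Of 35 genes of G1/S and DNA replication 20 fell and 1 rose, among them the cyclins Ccnd3 (-0.84 ± 0.04), Ccnd2 (-0.36 ± 0.05) and Ccnd1 (-0.34 ± 0.05). Camera, limma's competitive test, gave an adjusted p of 1.4e-04 to both lists, which became an adjusted p = 0.617 for G2/M and 0.348 for G1/S with an estimated correlation. Fibroblast markers fell in the same comparison: 10 of 11 were lower (11 adjusted over the list alone), including Lum (-0.40 ± 0.05), Col1a2 (-0.31 ± 0.05) and Dcn (-0.27 ± 0.05). Their camera adjusted p was 1.4e-04 (adjusted p = 0.348 with an estimated correlation). Endothelial markers fell too, 8 of 10 with 1 rising, led by Kdr (-0.97 ± 0.07) and Tie1 (-0.62 ± 0.12). Camera's adjusted p for them was 0.0037 (adjusted p = 0.348 with an estimated correlation).

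Of 20 interferon response genes 16 rose and 1 fell, with a median of 0.27. Rsad2 rose by 1.04 ± 0.06, Cxcl10 by 0.56 ± 0.05 and the RNA sensor gene Ddx58 by 0.55 ± 0.04. By camera the adjusted p was 1.6e-07 (adjusted p = 0.348 with an estimated correlation). Of 12 macrophage and leukocyte markers 3 fell and 0 rose, with a median of -0.35, and 1 fell without scramble replicate 1 or double knockdown replicate 1. Of 22 sarcomere genes 12 rose and 1 fell, led by Myl4, Myl7 (0.89 ± 0.08), Nebl (0.57 ± 0.07) and Des (0.34 ± 0.05). The list passed camera at an adjusted p of 0.0014 (adjusted p = 0.495 with an estimated correlation). Natriuretic peptide and hypertrophic markers gave 1 rise and 1 fall of 8 (Fhl1 at 0.36 ± 0.10, Myh7 at -0.15 ± 0.05). That total of 2 was 1 without scramble replicate 3 or double knockdown replicate 1 or 2, and 4 with only the groups compared.

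Of 17 unfolded protein and integrated stress response genes 11 fell and 2 rose. Tested by camera, this list had an adjusted p of 4.7e-04 (adjusted p = 0.348 with an estimated correlation). The chaperone gene Calr fell by 0.49 and the stress transcription factor genes Ddit3 and Atf5 fell by 0.46 and 0.34, while the co-chaperone gene Dnajb9 rose by 0.78 ± 0.06. Calcium handling and ion channel genes gave 9 falls and 2 rises of 18, among them Pln (-0.32 ± 0.04) and the gap junction gene Gja1 (-0.28 ± 0.04). For this list camera's adjusted p was 0.0014 (adjusted p = 0.233 with an estimated correlation). Fatty acid oxidation genes gave 9 falls and 1 rise of 18, including Cd36 (-0.45 ± 0.04) and Ppargc1a (-0.45 ± 0.06), with a camera adjusted p of 0.018 (adjusted p = 0.495 with an estimated correlation). Of 18 p53 targets 7 fell and 2 rose, led by Fas (-0.97 ± 0.07), with a camera adjusted p of 0.032 (adjusted p = 0.495 with an estimated correlation); this call ended without replicate 2 or 3 of the double knockdown (adjusted p = 0.056 and 0.071). The BTG/TOB list, whose members include both targets, gave 2 falls and 1 rise of 5 (3 falls adjusted over the list alone). Its camera adjusted p was 0.018 (adjusted p = 0.348 with an estimated correlation), and the member that rose was Btg3 (0.20 ± 0.06).

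Other lists did not pass camera in the double knockdown. CCR4-NOT and PAN deadenylase genes gave 3 rises and 2 falls of 13, cell cycle inhibitors 2 rises and 5 falls of 10 (6 falls adjusted over the list alone) with Cdkn1c at 0.59 ± 0.06, and DNA damage repair 1 rise and 3 falls of 15. Oxidative phosphorylation gave 3 rises and 2 falls of 21, glycolysis 3 rises (4 adjusted over the list alone) and 5 falls of 17 with Pfkp at 0.62 ± 0.04, and cholesterol synthesis 7 rises and 1 fall of 17. Immediate early genes gave 3 rises and 3 falls of 14, YAP targets 2 and 3 of 9, and inflammatory genes 1 rise and 5 falls of 16. The cholesterol list passed camera without scramble replicate 3 (adjusted p = 0.012) or double knockdown replicate 1 (0.024), and with the replicate block (0.048). The inflammatory list passed camera without double knockdown replicate 1 (adjusted p = 0.0064). Smooth muscle and myofibroblast markers gave 3 rises and 1 fall of 6, epicardial markers 1 and 1 of 5, and Schwann and neuronal markers 0 rises and 2 falls of 3. None of 4 erythroid markers passed edgeR, and 0 had an unadjusted p under 0.05 (smallest 0.23, Hba-a2, at -0.57 ± 0.46). DESeq2 and limma called 0 of them too. Oxidative phosphorylation gave 6 rises and 2 falls with DESeq2 and with limma on either TPM scale, where limma called 3 deadenylase genes and 4 inhibitors. With the stricter filter, or only the groups compared, 1 Schwann gene was called. Without scramble replicate 1, 2 deadenylase and 5 glycolysis genes were called. Without scramble replicate 2, 3 inhibitor, 2 repair and 1 Schwann gene were called. Without scramble replicate 3, 3 deadenylase, 4 inhibitor and 5 glycolysis genes were called. Without double knockdown replicate 1 the counts were 2 deadenylase, 3 inhibitor, 2 repair and 1 Schwann gene. Without its replicate 2 they were 2 deadenylase and 2 smooth muscle genes, and without its replicate 3 they were 1 Schwann gene. In all, 4873 genes passed edgeR's quasi-likelihood test, 2429 higher and 2444 lower, of which 350 and 401 changed at least 1.5-fold.

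Btg1 knockdown against scramble asked what changed when Btg1 alone was reduced. Snap91 rose from 33.0 ± 8.27 to 125 ± 10.8 CPM and Myl4 from 58.5 ± 0.630 to 178 ± 6.16 CPM (SD, n = 3 each). Lmcd1 rose from 58.5 ± 1.42 to 172 ± 26.1 CPM, and the transcription factor gene Creb5 from 7.41 ± 0.905 to 21.9 ± 3.92 CPM (SD, n = 3 each). Colec12 fell from 44.1 ± 1.24 to 11.2 ± 1.83 CPM and Emc4 from 84.2 ± 0.872 to 27.0 ± 2.55 CPM (SD, n = 3 each). Mitotic, interferon response, sarcomere and hypertrophic genes mostly rose, and unfolded protein response genes mostly fell.

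On the log2 scale the rises were 1.92 ± 0.16 for Snap91, 1.60 ± 0.07 for Myl4, 1.55 ± 0.12 for Creb5, 1.55 ± 0.13 for Lmcd1 and 1.45 ± 0.07 for Cnn1, with edgeR adjusted p-values of 1.5e-11 (Myl4) to 1.3e-05 (Snap91). After Btg1 itself, the falls were -1.97 ± 0.09 for Colec12, -1.64 ± 0.05 for Emc4, -1.47 ± 0.09 for Slc25a34 and -1.45 ± 0.13 for Efhd1, with edgeR adjusted p-values of 5.0e-16 (Emc4) to 1.3e-08 (Efhd1). The test called 4571 genes, 2342 higher and 2229 lower, of which 415 and 329 changed at least 1.5-fold.

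Of 33 G2/M genes 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.35, including Prc1 (0.73 ± 0.10), Ect2 (0.71 ± 0.11) and Ccnb1 (0.41 ± 0.08). Camera gave the list an adjusted p of 1.5e-05 (adjusted p = 0.437 with an estimated correlation). Of 35 G1/S and replication genes 19 rose and 3 fell, with Mcm6 at 0.50 ± 0.08, E2f1 at 0.62 ± 0.11 and Ccnd3, in the other direction, at -0.70 ± 0.04. Camera's adjusted p for them was 0.012 (adjusted p = 0.437 with an estimated correlation). DNA damage repair genes gave 7 rises of 15 (10 adjusted over the list alone), including Xrcc2 (0.64 ± 0.12) and Fancd2 (0.39 ± 0.10). By camera the adjusted p was 0.0074 (adjusted p = 0.362 with an estimated correlation). The mean of the G2/M list overlapped between groups: relative to scramble it was 0.33, 0.14 and 0.45 in Btg1 knockdown replicates 1 to 3 and -0.13, -0.01 and 0.15 in the scramble replicates. Without replicate 3 of the Btg1 knockdown, 13 G2/M genes rose, 11 G1/S genes rose and 3 repair genes rose, and without scramble replicate 1 12 G1/S genes and 3 repair genes rose. Fibroblast markers fell in this comparison, 9 of 11 (10 adjusted over the list alone), led by Lum (-0.30 ± 0.05) and Col1a2 (-0.22 ± 0.05). The list passed camera at an adjusted p of 0.0015 (adjusted p = 0.362 with an estimated correlation).

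Of 20 interferon response genes 18 rose and 0 fell, with Rsad2 at 1.07 ± 0.06, Ddx58 at 0.65 ± 0.04, Cxcl10 at 0.61 ± 0.05 and Usp18 at 0.52 ± 0.04. Tested by camera, this list had an adjusted p of 1.1e-10 (adjusted p = 0.362 with an estimated correlation). Of 12 macrophage and leukocyte markers 3 fell and 0 rose, with a median of -0.37. That list did not pass camera (adjusted p = 0.071), but did without scramble replicate 3 (0.027) or Btg1 knockdown replicate 3 (0.048). It also passed with camera on log2(TPM + 1) (adjusted p = 0.037) and with fry (0.0024). Sarcomere genes gave 14 rises and 2 falls of 22 (15 rises adjusted over the list alone), with Csrp3 at 0.60 ± 0.06 and Myom1 at 0.35 ± 0.05. For this list camera's adjusted p was 9.1e-06 (adjusted p = 0.362 with an estimated correlation). Hypertrophic markers gave 6 rises and 1 fall of 8 (7 rises adjusted over the list alone), with the Z-disc gene Xirp2 at 1.35 ± 0.15 and Fhl1 at 1.14 ± 0.10, with a camera adjusted p of 7.9e-04 (adjusted p = 0.362 with an estimated correlation). YAP targets gave 5 rises and 2 falls of 9, with Ccn1 at 0.78 ± 0.05 and Tgfb2 at 0.80 ± 0.10, with a camera adjusted p of 0.021 (adjusted p = 0.437 with an estimated correlation). Immediate early genes gave 8 rises and 2 falls of 14, with Atf3 at 0.94 ± 0.07, Egr1 at 0.50 ± 0.06 and Klf4 at -0.59 ± 0.05. Their camera adjusted p was 0.012 (adjusted p = 0.362 with an estimated correlation).

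Unfolded protein and stress response genes gave 12 falls and 1 rise of 17, with Calr at -0.58 ± 0.04, Herpud1 at -0.42 ± 0.04 and Atf5 at -0.41 ± 0.04. Camera's adjusted p for them was 1.5e-05 (adjusted p = 0.362 with an estimated correlation). Cholesterol synthesis genes gave 11 rises and 1 fall of 17. By camera the adjusted p was 0.0015 (adjusted p = 0.416 with an estimated correlation). Fatty acid oxidation genes gave 8 falls (9 adjusted over the list alone) and 2 rises of 18, with Cpt1a at -0.46 ± 0.04. The list passed camera at an adjusted p of 0.021 (adjusted p = 0.434 with an estimated correlation). Smooth muscle and myofibroblast markers gave 2 rises (Cnn1 and Tagln, the latter at 0.62 ± 0.05) and 1 fall of 6. Tested by camera, this list had an adjusted p of 0.021 (adjusted p = 0.362 with an estimated correlation). Pln (-0.37 ± 0.04) and Gja1 (-0.58 ± 0.04), the main ventricular gap junction gene, fell, although the calcium and channel list as a whole, with 4 rises (5 adjusted over the list alone) and 7 falls of 18, did not pass camera (adjusted p = 0.138).

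Btg2 knockdown against scramble asked the same of Btg2. Plcb2, a phospholipase C gene, rose from 10.4 ± 0.624 to 24.2 ± 0.327 CPM and Fgf23, a phosphate-regulating hormone gene, from 13.2 ± 0.226 to 28.8 ± 4.2 CPM (SD, n = 3 each). Stc1, a secreted glycoprotein gene, fell from 133 ± 15.8 to 60.5 ± 2.11 CPM and Leprotl1 from 47.5 ± 4.50 to 21.5 ± 2.20 CPM (SD, n = 3 each). Mitotic and replication genes and macrophage markers mostly fell where they changed, and sarcomere and hypertrophic genes mostly rose.

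The largest rises on the log2 scale were Frmpd1 (1.26 ± 0.13), Plcb2 (1.22 ± 0.09), the matrix gene Vwa1 (1.17 ± 0.10), Fgf23 (1.13 ± 0.09) and Prima1 (1.04 ± 0.10), with edgeR adjusted p-values of 1.7e-09 (Plcb2) to 9.2e-08 (Frmpd1). The largest falls were the matrix metalloproteinase genes Mmp13 (-1.37 ± 0.38, edgeR adjusted p = 0.025) and Mmp9 (-1.18 ± 0.28, adjusted p = 0.013), Tcaim (-1.15 ± 0.09), Stc1 (-1.14 ± 0.07) and Leprotl1 (-1.13 ± 0.08). The call of Mmp13 ended without any 1 of the scramble replicates or Btg2 knockdown replicate 1 or 3 (adjusted p = 0.052 to 0.095), and that of Mmp9 without Btg2 knockdown replicate 3 (0.053). The test called 3760 genes, 2051 higher and 1709 lower, of which 201 and 175 changed at least 1.5-fold; scaled by library size alone, 1579 were higher and 2248 lower.

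Of 33 G2/M genes 19 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.33, including Ttk (-0.65 ± 0.12), Racgap1 (-0.51 ± 0.11) and Cdc20 (-0.42 ± 0.07). For this list camera's adjusted p was 3.9e-06 (adjusted p = 0.704 with an estimated correlation). Of 35 G1/S and replication genes 16 fell and 2 rose (18 and 2 adjusted over the list alone), with the licensing genes Cdc6 at -0.88 ± 0.14 and Cdt1 at -0.73 ± 0.11, with a camera adjusted p of 1.3e-04 (adjusted p = 0.615 with an estimated correlation). Without scramble replicate 3, 11 G2/M genes fell and 11 G1/S genes changed, and without Btg2 knockdown replicate 1, 12 G2/M genes fell and 9 G1/S genes fell. Macrophage and leukocyte markers gave 7 falls of 12, with the complement genes C1qc at -1.25 ± 0.30 and C1qa at -1.0 ± 0.24, with a camera adjusted p of 0.0021 (adjusted p = 0.332 with an estimated correlation); 4 fell without scramble replicate 1 or Btg2 knockdown replicate 2. Fibroblast markers gave 5 falls and 1 rise of 11, with Pdgfra and Tcf21 both at -0.33, and did not pass camera (adjusted p = 0.299). Without scramble replicate 2, 3 fibroblast markers fell.

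Sarcomere genes gave 12 rises and 0 falls of 22 (14 and 0 adjusted over the list alone), with the slow myosin heavy chain gene Myh7 at 0.52 ± 0.05, Nebl at 0.44 ± 0.07 and Myl4 at 0.38 ± 0.07. Their camera adjusted p was 1.3e-04 (adjusted p = 0.615 with an estimated correlation). Hypertrophic markers gave 6 rises of 8, with Ankrd1 at 0.44 ± 0.06 and the atrial natriuretic peptide gene Nppa at 0.36 ± 0.08. Camera's adjusted p for them was 6.8e-05 (adjusted p = 0.615 with an estimated correlation). YAP targets gave 5 rises of 9, with Crim1 at 0.49 ± 0.05. By camera the adjusted p was 0.0025 (adjusted p = 0.615 with an estimated correlation). Immediate early genes gave 8 rises of 14, with Atf3 at 0.52 ± 0.07 and Fos at 0.45 ± 0.08. The list passed camera at an adjusted p of 0.0032 (adjusted p = 0.332 with an estimated correlation). With library size alone or without scramble replicate 3, 5 immediate early genes rose.

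Oxidative phosphorylation genes gave 8 falls of 21 (9 adjusted over the list alone), led by Ndufa4 (-0.66 ± 0.05). Tested by camera, this list had an adjusted p of 0.0038 (adjusted p = 0.704 with an estimated correlation). This count was 4 without scramble replicate 2 or Btg2 knockdown replicate 3, and 5 without scramble replicate 3 or Btg2 knockdown replicate 1. Inflammatory genes gave 5 falls of 16, with Cxcl12 at -0.38 ± 0.05. For this list camera's adjusted p was 0.024 (adjusted p = 0.718 with an estimated correlation), a call that ended without scramble replicate 1 (0.067) or Btg2 knockdown replicate 3 (0.081). The inflammatory list did not pass with fry (adjusted p = 0.12). Smooth muscle markers gave 1 rise of 6, Cnn1 at 0.96 ± 0.07, with a camera adjusted p of 0.043 (adjusted p = 0.615 with an estimated correlation), which ended without scramble replicate 1 (0.065) or Btg2 knockdown replicate 2 (0.069). Without Btg2 knockdown replicate 3, with DESeq2, limma or only the groups compared, 2 of these markers rose. With only the groups compared, 7 inflammatory genes fell and 1 rose. Interferon response genes gave 3 rises and 7 falls of 20 (8 falls adjusted over the list alone), with Irf7 at -0.33 ± 0.04 and Rsad2 at 0.31 ± 0.06, and did not pass camera (adjusted p = 0.156). Without Btg2 knockdown replicate 1 or 2, or with limma, 6 interferon genes were called. Slc8a1 (0.42 ± 0.04) and Ryr2 (0.31 ± 0.04) rose, within a calcium and channel list that gave 6 rises and 5 falls of 18.

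Double knockdown against the Btg1 knockdown asked what the Btg2 siRNA added where Btg1 was already reduced. Mitotic and replication genes mostly fell. Cdk1, the mitotic cyclin-dependent kinase, fell by 0.74 on the log2 scale, Ccnb1 by 0.73 and Plk1 by 0.86. Of 33 G2/M genes 30 fell and 0 rose, with a median of -0.68. Of 35 G1/S and replication genes 27 fell and 0 rose (29 and 0 adjusted over the list alone), including E2f1 (-0.96 ± 0.11), Cdt1 (-0.88 ± 0.10) and Mcm6 (-0.71 ± 0.08).

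Camera gave adjusted p-values of 9.1e-22 to G2/M and 1.6e-15 to G1/S (adjusted p = 0.184 and 0.0928 with an estimated correlation). Repair genes gave 8 falls of 15 (11 adjusted over the list alone), with Brca1 at -0.77 ± 0.14, with a camera adjusted p of 3.2e-06 (adjusted p = 0.154 with an estimated correlation). Immediate early genes gave 9 falls of 14 (10 adjusted over the list alone), with Egr1 at -0.62 ± 0.06. Their camera adjusted p was 2.5e-05 (adjusted p = 0.0928 with an estimated correlation). Fibroblast markers gave 2 falls of 11, Ddr2 (-0.23 ± 0.05) and Tcf21 (-0.17 ± 0.06), and did not pass camera (adjusted p = 0.186), but did without Btg1 knockdown replicate 2 (0.019) or double knockdown replicate 1 (0.021). Only 1 was called without Btg1 knockdown replicate 1 or 3 or double knockdown replicate 2, and with library size alone, no filter, only the groups compared, the replicate block or limma. Endothelial markers fell with the mitotic genes, 5 of 10 (6 adjusted over the list alone), led by Kdr (-0.56 ± 0.07) and Tie1 (-0.40 ± 0.12), with a camera adjusted p of 0.012 (adjusted p = 0.315 with an estimated correlation). Of these markers 2 fell without Btg1 knockdown replicate 1 or double knockdown replicate 2, and 3 without Btg1 knockdown replicate 3, with only the groups compared or with limma. By edgeR, 2791 genes changed, 1297 higher and 1494 lower. Beside Btg2 (-1.35 ± 0.04) and Btg1 (-0.36 ± 0.05), the largest falls were Creb5 (-1.27 ± 0.12), Tcaim (-1.23 ± 0.09), Leprotl1 (-1.18 ± 0.08) and Stc1 (-1.09 ± 0.07), and the largest rises were Plcb2 (1.07 ± 0.09), Ctla2a (0.94 ± 0.11), Prima1 (0.94 ± 0.11), Card10 (0.83 ± 0.10) and B3gnt7 (0.82 ± 0.07), all at an edgeR adjusted p of 5.6e-06 (Btg1) or below.

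Double knockdown against the Btg2 knockdown asked what the Btg1 siRNA added. Interferon response genes rose, 17 of 20 with 1 falling (18 rises adjusted over the list alone), with Oas1a at 0.55 ± 0.04, Ddx58 at 0.52 ± 0.04 and Isg15 at 0.50 ± 0.05. The interferon-inducible GTPase gene Ifi47 rose from 37.8 ± 1.09 to 86.6 ± 2.60 CPM (SD, n = 3 each). Myh7 fell by 0.67 and Ryr2 by 0.45 on the log2 scale. Of the 33 G2/M genes 3 rose and 1 fell, with a median of 0.00, and 1 rose and 1 fell without Btg2 knockdown replicate 1.

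Camera gave the interferon list an adjusted p of 2.8e-12 (adjusted p = 0.231 with an estimated correlation), and macrophage markers gave 2 rises of 12 (0 adjusted over the list alone, by edgeR), Lyz2 (0.41 ± 0.13) and Csf1r (0.48 ± 0.17), without passing camera (adjusted p = 0.128). The macrophage count was 1 without Btg2 knockdown replicate 1 or 3, 0 by edgeR without Btg2 knockdown replicate 2 or double knockdown replicate 2, and 5 without double knockdown replicate 1. Fibroblast markers gave 8 falls and 1 rise of 11, with Col1a2 at -0.42 ± 0.05. Camera's adjusted p for them was 0.0079 (adjusted p = 0.423 with an estimated correlation), and 5 fell without Btg2 knockdown replicate 2. Endothelial markers gave 2 falls of 10 (5 adjusted over the list alone) and 4 without double knockdown replicate 1 or 3. The endothelial list had a camera adjusted p of 0.030 (adjusted p = 0.423 with an estimated correlation), a call that ended without Btg2 knockdown replicate 2 (0.055) or double knockdown replicate 2 (0.072). Oxidative phosphorylation genes gave 11 rises of 21, with Idh3a at 0.19 ± 0.04. By camera the adjusted p was 0.0037 (adjusted p = 0.423 with an estimated correlation). By edgeR, 4039 genes changed, 1909 higher and 2130 lower, and scaled by library size alone 2443 were higher and 1758 lower. The largest rises were Reep6 (1.25 ± 0.15), Myl4 (1.2 ± 0.07), Ifi47 (1.2 ± 0.07), Abcb9 (1.18 ± 0.09) and Cited1 (1.05 ± 0.08), at edgeR adjusted p-values of 2.5e-10 (Ifi47) to 9.1e-07 (Reep6). The largest falls were Btg1 (-2.53 ± 0.05), Prrg4 (-1.85 ± 0.08), Slc9a3 (-1.82 ± 0.14), Emc4 (-1.74 ± 0.06) and Brinp2 (-1.74 ± 0.16), at edgeR adjusted p-values of 1.6e-21 (Btg1) to 3.2e-08 (Brinp2).

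Btg1 knockdown against Btg2 knockdown compared the single knockdowns, which carried equal doses of scramble. Of 33 G2/M genes 30 were higher with the Btg1 siRNA and 0 lower (31 and 0 adjusted over the list alone), with a median of 0.61, including Ttk (0.97 ± 0.12), Ccnb1 (0.78 ± 0.09) and Aurka (0.76 ± 0.09). Of 35 G1/S and replication genes 24 were higher and 3 lower, with Mcm6 at 0.88 ± 0.08 and Ccnd3 at -0.61 ± 0.04. Of 20 interferon response genes 18 were higher and 0 lower, with Oas1a at 0.73 ± 0.04 and Irf7 at 0.56 ± 0.04. The mean of the macrophage and leukocyte markers was also higher with the Btg1 siRNA, but that list did not pass camera or fry. Relative to scramble their mean was -0.277 ± 0.058 with the Btg1 siRNA and -0.503 ± 0.055 with the Btg2 siRNA (SD, n = 3 each). Gja1 (-0.75 ± 0.04) and Myh7 (-0.65 ± 0.05) were lower with the Btg1 siRNA.

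Camera gave adjusted p-values of 9.4e-13 to G2/M, 1.2e-06 to G1/S and 2.8e-12 to interferon response (adjusted p = 0.467, 0.452 and 0.452 with an estimated correlation). Fibroblast markers gave 2 rises and 5 falls of 11 (6 falls adjusted over the list alone), with a median of -0.15, and did not pass camera (adjusted p = 0.171), but did without Btg1 knockdown replicate 3 (0.034). By edgeR, 5120 genes differed, 2540 higher and 2580 lower, and scaled by library size alone 2911 were higher and 2143 lower. Among the largest differences upward were Snap91 (1.57 ± 0.16), Abcb9 (1.49 ± 0.09), Asb4 (1.44 ± 0.16) and Sypl2 (1.38 ± 0.09), at edgeR adjusted p-values of 1.3e-11 (Abcb9) to 4.0e-05 (Snap91). Downward they were Lrat (-2.31 ± 0.27), Brinp2 (-2.24 ± 0.16), Slc9a3 (-2.20 ± 0.14), Btg1 (-2.18 ± 0.04) and Frmpd1 (-2.02 ± 0.13), at edgeR adjusted p-values of 2.9e-20 (Btg1) to 1.3e-05 (Lrat).

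**Figure D4:**
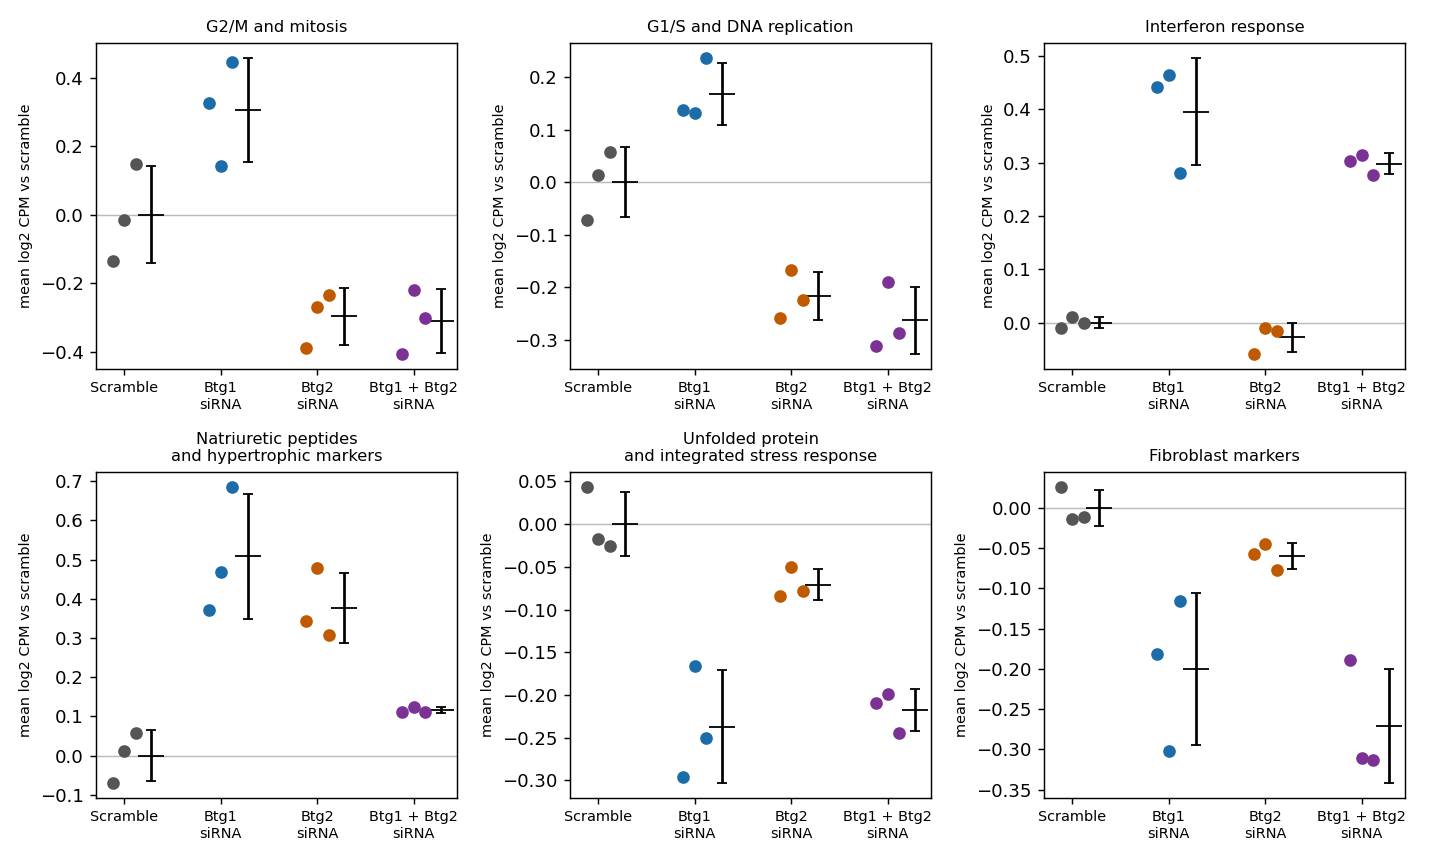
Mean log2 CPM of 6 gene lists in each library, relative to the mean of the scramble libraries, with points for libraries and bars for the mean and SD of each group (n = 3). The G2/M list lies above scramble on average in the Btg1 knockdown, with 1 library (0.14) within the scramble range, and below it in the groups with the Btg2 siRNA. The interferon list is higher in both groups with the Btg1 siRNA, with group means of 0.396 (Btg1 knockdown) and 0.298 (double knockdown).

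The interaction asked whether the double knockdown differed from the sum of the single knockdowns. Hypertrophic markers were below that sum in all 8 tested genes, with a median of -0.61. Xirp2 stood at 220 ± 9.21 CPM in scramble, 561 ± 112 in the Btg1 knockdown, 316 ± 37.9 in the Btg2 knockdown and 269 ± 25.6 in the double knockdown (SD, n = 3 each). Immediate early genes and YAP targets were below the sum too, with Egr1 at -0.90 ± 0.08 and Ccn1 at -0.75 ± 0.07 on the log2 scale. Btg1 (-0.44 ± 0.06) and Btg2 (-0.65 ± 0.06) were themselves lower in the double knockdown than the sum.

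Immediate early genes gave 9 falls of 14 (10 adjusted over the list alone), with Nr4a1 at -0.98 ± 0.10 and Atf3 at -0.83 ± 0.09. The list passed camera at an adjusted p of 1.2e-08, and with an estimated correlation the adjusted p was 0.0263, the only list in any of the 7 comparisons to pass that way. Hypertrophic markers passed camera at 1.5e-10 (adjusted p = 0.132 with an estimated correlation), with Fhl1 at -1.0 ± 0.14 and Rcan1 at -0.64 ± 0.08. YAP targets gave 7 falls of 9, with Tgfb2 at -1.05 ± 0.14. Tested by camera, this list had an adjusted p of 7.3e-08 (adjusted p = 0.146 with an estimated correlation). Sarcomere genes gave 12 falls and 1 rise of 22 (13 falls adjusted over the list alone), with Csrp3 at -0.72 ± 0.09 and Myh7 at -0.55 ± 0.07. For this list camera's adjusted p was 3.0e-06 (adjusted p = 0.299 with an estimated correlation). G2/M genes gave 8 falls of 33 (14 adjusted over the list alone), led by Prc1 (-0.64 ± 0.14), with a camera adjusted p of 5.0e-06 (adjusted p = 0.536 with an estimated correlation), and macrophage markers gave 3 rises of 12 (7 adjusted over the list alone), led by Lyz2 (0.94 ± 0.18), with a camera adjusted p of 7.2e-04 (adjusted p = 0.132 with an estimated correlation). The number of G2/M genes below the sum was 13 without scramble replicate 3 or Btg1 knockdown replicate 2. It was 4 without scramble replicate 2, Btg2 knockdown replicate 2 or double knockdown replicate 3. It was 3 without scramble replicate 1, Btg1 knockdown replicate 1 or 3, Btg2 knockdown replicate 3 or double knockdown replicate 1, and 5 with library size alone. With limma on either TPM scale it was 2. Without double knockdown replicate 1, 6 macrophage markers were above the sum. By edgeR, 1890 genes departed from the sum, 626 above and 1264 below it, and scaled by library size alone 1004 were above and 1016 below. The largest departures upward were Dhrs7c (1.18 ± 0.21), Lyz2, Gstm7 (0.78 ± 0.17), Cmbl (0.76 ± 0.18) and Tmod4 (0.74 ± 0.16), at edgeR adjusted p-values of 4.3e-04 (Dhrs7c) to 0.0048 (Cmbl). Downward they were Creb5 (-1.68 ± 0.17), Ankrd23 (-1.62 ± 0.18), Xirp2 (-1.58 ± 0.21), Ino80d (-1.5 ± 0.16) and Lpp (-1.46 ± 0.14), at edgeR adjusted p-values of 1.6e-07 (Lpp) to 0.0014 (Xirp2).

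Fold changes against the same scramble libraries were then set side by side across the 12535 genes, which are not independent replicates. Double and Btg1 knockdown changes had a Pearson correlation of 0.693 and a covariance of 0.0889, against 0.512 and 0.0136 in 20 simulations of unchanged groups sharing those controls. Double and Btg2 knockdown changes had 0.503 and 0.0534, against 0.494 and 0.0134. Btg1 and Btg2 knockdown changes had 0.330 and 0.0356, against 0.503 and 0.0136. Double and Btg1 knockdowns shared 1483 genes called higher and 1435 called lower, against 454 and 435 for independent lists. Double and Btg2 knockdowns shared 1089 and 945, against 397 and 333. Btg1 and Btg2 knockdowns shared 931 called higher and 556 called lower, against 383 and 304. Genes called in opposite directions numbered 94 for double and Btg1, 262 for double and Btg2 and 475 for Btg1 and Btg2, against 889, 731 and 684 for independent lists. The simulated groups carried no siRNA effects, so their correlations are not a fair reference for the observed ones. Their covariance estimates the part from the shared controls. The observed covariance exceeded it by 0.0753 (double and Btg1), 0.0400 (double and Btg2) and 0.0219 (Btg1 and Btg2). With 3 scramble libraries the controls could not be split, so part of the excess of shared calls over independent lists may come from the shared controls.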

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

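The tests of explanations, the regroupings of libraries and the permuted residuals in this part were chosen after the results were seen, while the interaction and its lists were set before. The results listed here were singled out because the test of the difference itself, the interaction, separated the effect of one siRNA in the presence and absence of the other. It called 1890 genes. Of 100 groupings of the 12 libraries, only 1, the real one, gave as many, and the highest other gave 59 (at an unadjusted p under 0.05, 3548 and 2513). These splits do not test additivity, because they leave the siRNA effects in the spread: the biological coefficient of variation was 4.97% in the real grouping and at least 9.61% in the others. With the additive effects kept and their residuals permuted over the libraries, limma on log2 CPM called 1868 genes in the real order and at most 50 in the other orders. Of 100 orders only 1, the real one, gave as many, which argues against chance for that count but does not exclude it. The residuals of the additive fit still hold any real departures, which widen the spread in the other orders. At an unadjusted p under 0.05 the real order had 3569 genes and the highest other 2385. Among genes the departures from additivity were Dhrs7c at 1.18, Lyz2 at 0.94, Gstm7 at 0.78, Cmbl at 0.76 and Tmod4 at 0.74 on the log2 scale. In the other direction they were Creb5 at -1.68, Ankrd23 at -1.62, Xirp2 at -1.58, Ino80d at -1.5 and Lpp at -1.46, and the targets Btg1 at -0.44 and Btg2 at -0.65.

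Among the lists fixed before the data were examined, 11 of 26 passed camera in the interaction, and with an estimated correlation 1 did, the immediate early genes (adjusted p = 0.0263). Their median log2 departures were -0.24 for the BTG/TOB family, -0.16 for G1/S and DNA replication, -0.32 for G2/M and mitosis, -0.32 for DNA damage repair and -0.24 for sarcomere genes. They were -0.61 for natriuretic peptide and hypertrophic markers, -0.43 for immediate early genes, -0.57 for YAP targets and -0.43 for smooth muscle and myofibroblast markers. Above the sum were unfolded protein response genes at 0.069 and macrophage and leukocyte markers at 0.56. With an estimated correlation the adjusted p was 0.132 for the hypertrophic and the macrophage lists, 0.137 for BTG/TOB, 0.146 for YAP targets, 0.189 for smooth muscle and 0.299 for sarcomere genes. It was 0.353 for G1/S, repair and unfolded protein genes and 0.536 for G2/M, whose call was also lost with fry (0.11). The call of the unfolded protein list ended without scramble replicate 1 (adjusted p = 0.058) or Btg1 knockdown replicate 1 (0.063). The BTG/TOB list includes both siRNA targets, Btg1 (-0.44) and Btg2 (-0.65), so its departure is not separate from theirs.

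For the 6 comparisons of single groups, the 6 libraries make 10 splits, too few for a share under 0.05. The real split of double knockdown and scramble called 4873 genes, and the counts for the others were 4571 (Btg1 against scramble), 3760 (Btg2 against scramble), 2791 (double against Btg1), 4039 (double against Btg2) and 5120 (Btg1 against Btg2). The highest of the other 9 splits called 0 genes by edgeR in each of the 6, where 1 of 10 splits, the real one, gave as many as the real count. At an unadjusted p under 0.05 the highest other splits had 394 to 1083 genes, against 4273 to 6023 in the real ones. Each of the other splits mixed the groups compared and so left the siRNA effects in the spread. Their low counts were therefore fixed in advance and are no support for the real counts.

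Cell cycle genes were higher with the Btg1 siRNA than with the Btg2 siRNA, with a G2/M median of 0.61. Without the deepest and the shallowest library it was 0.59, which argues against depth. A larger share of fibroblasts would raise their markers by about as much, and the fibroblast median was -0.15. The knockdowns themselves, effects of either siRNA on other transcripts, and the cell type in which these genes changed stay open, and may act together.

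Departures below the sum outnumbered those above it in the interaction, 1264 against 626. For the whole set the scaling may account for this, since the share below was 50.3% with library size alone, against 66.9%. Among departures of at least 1.5-fold (333 against 68) the share below stayed at 78.7%, so scaling does not account for those. With a correction for gene length per library the shares were 62.0% and 83.4%, which argues against length as the whole cause. A limit on how far a shared response can rise is a biological explanation that was not tested. Both targets were also lower in the double than in the single knockdowns. Btg1 stood at 51.7 against 66.2 CPM and Btg2 at 68.7 against 85.2. The design cannot separate this deeper knockdown from a departure from additive effects.

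Interferon response genes were higher in both groups with the Btg1 siRNA. More leukocytes would raise their markers, whose medians were -0.37 in the Btg1 knockdown (SD 0.27 across 12 markers) and -0.35 in the double knockdown (SD 0.34). These medians are against scramble. Between the single knockdowns the mean of the markers was higher with the Btg1 siRNA (-0.277 and -0.503 relative to scramble). The list did not pass camera or fry there, and leukocytes stay open for that contrast. For the Btg1 knockdown, a lower scramble dose is argued against by the single knockdowns, which had equal doses and differed in 18 of 20 genes. The double knockdown alone received no scramble, so for that group the dose stays open. A response to the Btg1 siRNA itself and a response to the reduction of Btg1 cannot be told apart, because each gene had 1 siRNA product, whose number of duplexes the labels do not give: 17 of 20 were higher in the double than in the Btg2 knockdown, as both would give. Either may be the source, and in the double knockdown so may the absence of scramble.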

How the results depend on the processing

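No alternative in this part was chosen after the results were seen. Every comparison's gene count stayed within 1.5 times its value under each alternative that was run. With only the groups compared, which was not run for the interaction, as planned, the counts moved by group. They fell to 4538 for double against scramble, 2155 for double against Btg1 and 3494 for double against Btg2. They rose to 5018 for Btg1, 4339 for Btg2 and 5382 for Btg1 against Btg2. Replicates differed most in the double knockdown (chi-square per degree of freedom 12.8 to 25.7), and the single fit shares one spread over all groups. Leaving out 1 library gave 4065 to 4862 genes for double against scramble, 3724 to 4054 for Btg1, 2839 to 3302 for Btg2, 2017 to 3047 for double against Btg1, 3365 to 3840 for double against Btg2, 4277 to 4673 for Btg1 against Btg2 and 1340 to 1883 for the interaction. Btg1 and Btg2 kept their direction and side of the threshold in each comparison and alternative. No called gene that stayed called turned direction under them, nor did any list past camera. The balance of higher and lower genes did turn with library size alone, to 2238 and 2275 for Btg1, 1579 and 2248 for Btg2, 2443 and 1758 for double against Btg2 and 2911 and 2143 for Btg1 against Btg2. With limma on log2(TPM + 1) it turned for every comparison but Btg2 against scramble and the interaction, to 2305 and 2179 for double against scramble and 1174 and 1110 for double against Btg1, for example. The near-even balance of double against scramble also turned with DESeq2 (2506 and 2371), RLE scaling, no filter, only the groups compared and without each double knockdown replicate, and that of Btg1 against Btg2 without Btg2 knockdown replicate 2 or 3. Of the tests of named genes under alternatives, 11534 kept their side of the threshold, 389 fell below it and 124 rose above it, and for list tests these were 1834, 82 and 60. With an estimated correlation the lists past the threshold numbered 0 in the first 6 comparisons and 1 in the interaction, against 11, 13, 10, 8, 11, 7 and 11 with the preset value; at an unadjusted p under 0.05 they numbered 3, 3, 2, 5, 4, 1 and 6, and fry called 14, 19, 11, 10, 15, 10 and 11. That setting gives closely co-varying lists, such as G2/M (estimated correlation 0.607), far less weight by construction. Correlations of fold changes moved to 0.730 (double and Btg1) and 0.270 (Btg1 and Btg2) among genes with at least 5 CPM; the cause was not tested. The replicate numbers did not pair the libraries: 18 same-number correlations of deviations from group means ran from -0.092 to 0.060, and 5 of 12 libraries correlated best with their own number. With the replicate block the counts were 4759, 4455, 3650, 2659, 3919, 4985 and 1768, in the order above. Depth limits genes below 1 CPM, where changes of 2-fold were missed in simulated data.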

Other observations

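The tests and gene lists in this part were chosen after values had been seen. Atp1b2, a sodium pump beta subunit, fell by 1.34 on the log2 scale in the double knockdown and by 1.38 in the Btg1 knockdown, while in the Btg2 knockdown it was at -0.07 ± 0.06 (edgeR adjusted p = 0.43). Among sarcoglycans in the double knockdown, Sgcb (-1.47 ± 0.04) fell, while Sgca (0.00 ± 0.05), Sgcd (0.09 ± 0.06) and Sgce (-0.12 ± 0.06) did not pass edgeR.

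Imprinted genes were looked at because H19 was among the largest rises. Of 18 tested in the double knockdown, 8 rose and 4 fell, and 66.7% of the changed genes rising argues against a common direction. H19 (1.36 ± 0.12), Cdkn1c (0.59 ± 0.06), Plagl1 (0.56 ± 0.06) and Igf2r (0.28 ± 0.04) rose, and Mest (-0.54 ± 0.12) and Ndn (-0.31 ± 0.05) fell. In the Btg1 knockdown 4 rose and 3 fell, with H19 at 1.04 ± 0.12, Cdkn1c at 0.48 ± 0.06 and Mest at -0.99 ± 0.12. In the Btg2 knockdown 5 rose and 4 fell, with Plagl1 at 0.80 ± 0.06, Slc38a4 at 0.79 ± 0.10 and Ndn at -0.24 ± 0.05. H19 did not pass there (0.35 ± 0.13, edgeR adjusted p = 0.062), so its rise was not particular to the double knockdown but was called in both groups with the Btg1 siRNA.

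Myl4 and Myl7, atrial light chain genes, rose in the double knockdown, which raised the hypothesis of a general rise of atrial genes there. Of 7 other atrial genes tested, 0 passed edgeR upward and 0 downward, with Nppa at 0.06 ± 0.08 and Sln at -0.41 ± 0.19, which argues against it in the double knockdown. In the single knockdowns Nppa rose, by 0.29 ± 0.08 with the Btg1 siRNA and 0.36 ± 0.08 with the Btg2 siRNA. Of 9 atrial genes, Myl4 and Myl7 included, 3 rose and 1 fell in the Btg1 knockdown and 4 rose and 0 fell in the Btg2 knockdown.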
